A study of Homo sapiens with 12 samples.

How the data were processed

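Total RNA, streptavidin-bound RNA and footprints were sequenced in the negative control, APEX2-NES, H2B-APEX2 and Connexin43-APEX2 lines. Cells received 4-thiouridine and doxycycline for 16 h and biotin-phenol for 30 min before peroxide and ultraviolet light. The submitters named the genome build hg19, bcl2fastq 2.17.1 and TopHat, whose version is not given in the sources used here. The read counter, its annotation and the footprint cluster caller are likewise not given in the sources used here.

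The gene tables of 2016 and 2017 give expected counts and RPKM per gene as deposited. The expected counts were deposited with 0.001 standing for 0 reads, and 47.4% or more of the values above 0 per library are whole numbers. The RPKM values were computed by the authors by the listed gene length and a library total that lay above the sum of the listed reads in every library, with 1e-07 standing for 0. The footprint sheets hold deposited counts of clusters and of crosslinked reads per gene, in all and by 5' UTR, coding sequence, 3' UTR and intron. Long and short footprints are pooled in them. A gene at 0 there is one for which no cluster was called, since clusters were called per library. Columns were matched to samples by the names of the lines. The 2016 columns that carry the name of a line were taken as bound RNA and the column named total as total RNA shared by the lines.

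RNA values were log2(RPKM + 1) for genes with a mean RPKM of at least 1 over the libraries compared. Bound minus total RNA was formed per line and table, lines were subtracted, and each difference was centred on its median over tested genes. A gene passed when it differed at least 2-fold in the same direction in every table that holds both lines. With 12 groups of 1 sample, genes passed by size and no p-value is given for single genes. A limma fit that took both tables together was an alternative. The counting SE comes from the expected counts by the delta method. In all, 13 RNA and 6 footprint comparisons were made. Correlations across genes are Pearson's r.

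The 20 gene lists were written before the data were examined, as were the size rules, the filters, the alternatives and the rule for naming genes. A list's median was placed among 10000 random lists of the same size drawn from the same expression deciles. Lists with fewer than 3 measured genes have no value. The alternatives that remove the GC trend, fibroblast-like genes or genes listed at 0 were added later, as were the lists of fibroblast-like genes. The first (21 genes) was chosen after its values were seen, and the second (39 genes) was written before its values were looked at.

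The naming rule took the 10 highest and 10 lowest symbol-carrying genes past the 2-fold rule, ranked by the smaller difference over the tables, without pseudogenes, told by gene type or, outside protein-coding genes, by symbol, nuclear copies named MTRNR2L and unnamed clones. It added the 3 most abundant members of each list outside the central 95%, and GJA1, MALAT1 and NEAT1. For footprints it took 5 in each direction. Because many of these were listed at 0 in a library, the 10 highest and lowest protein-coding genes with reads in every library compared were named as well. That restriction, the symbol patterns that tell pseudogenes, and the naming of RNY1, CD151 and RNU2-2P, were chosen after their values were seen. An abundant gene was called listed at 0 when it had 0 reads in a library despite a median of 100 reads or more over all libraries, which held for 147 of 7467 genes of that abundance. No fold is given for such genes.

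Footprint reads per gene were compared as a share of the line's total for genes with at least 10 reads over the pair. A gene passed when the ratio was at least 4-fold and its exact 95% interval excluded 2-fold. Genes with reads in only 1 line were counted apart. Cluster shares have exact Clopper-Pearson 95% intervals. Sums over clusters depend on how many were called, and reads per cluster were 8.90 in the negative control, 12.8 in APEX2-NES, 13.0 in H2B-APEX2 and 11.7 in Connexin43-APEX2. Of 19892 genes, 18929 names were taken by Ensembl identifier from the RNA tables and 963 from the sheets, where 26 symbols had turned into dates. GC content was that of the longest transcript in GENCODE 29 on GRCh38, joined by Ensembl identifier without using coordinates. Coordinates given are hg19, counted from 1.

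Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The procedure was checked on simulated counts with 200 changed genes. These counts held Poisson counting error only and no variation between libraries, so the shares below are not error rates of the real comparisons. In H2B-APEX2 minus APEX2-NES, 8.82% of genes changed 2-fold, 87.3% changed 4-fold and 79.7% changed 8-fold passed the rule, and 18 of 4923 unchanged genes did. In Connexin43-APEX2 minus APEX2-NES these shares were 0%, 75.4% and 83.3%, with 0 of 5065 unchanged genes. Of 200 simulated lists without a change 4% fell outside the central 95%, and 100% of raised lists did. Footprint intervals covered the simulated ratio in 96.6% to 96.9% of genes, and 46.8% of genes changed 4-fold and 83.8% changed 8-fold passed in H2B-APEX2 against APEX2-NES. Of genes changed 4-fold, 26.2% passed in Connexin43-APEX2 against APEX2-NES and 25.8% in Connexin43-APEX2 against H2B-APEX2, and of those changed 8-fold 78.6% and 73.1%.

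Alternatives to the pseudocount, filter, centring, matching of random lists, table, use of total RNA, footprint minimum and footprint scaling were tried, and limma was fitted over both tables. RPKM recomputed from the expected counts with TMM factors of edgeR or size factors of DESeq2 was tried in place of the centring, and later together with it. Left out were leaving out single runs, since no runs were named, and long and short footprints apart, since they were deposited together. Raw reads were not analysed here.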

Results

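The series used Proximity-CLIP, which marks proteins near a chosen place in the cell with biotin and recovers the RNA crosslinked to them. The cells were HEK293 T-REx, a human embryonic kidney line with inducible transgenes. APEX2, an engineered peroxidase, was placed in the cytoplasm (APEX2-NES, with a nuclear export signal), on chromatin (H2B-APEX2) or at cell contacts (Connexin43-APEX2). A line without APEX2 served as the negative control. For each of the 4 lines there were 3 kinds of library: total RNA of the extract, RNA bound to streptavidin, and short footprints protected by RNA-binding proteins. That gave 12 samples in 12 groups of 1 sample each. Bound RNA of 3 lines stands both in a table of 2016 and in one of 2017, and the values of each table are given where both hold the lines compared. Whether these are independent replicates is not stated in the sources used here.

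The gene tables of 2016 and 2017 held 12 RNA libraries over 57773 genes. Bound RNA held 16938460 and 8959049 reads in Connexin43-APEX2 (2016 and 2017), 20674192 and 14584546 in APEX2-NES, 12054794 and 22952389 in the negative control, and 16529730 in H2B-APEX2, which only the 2017 table holds. Total RNA of 2017 held 47355589 reads in the negative control, 56785950 in APEX2-NES, 33672152 in H2B-APEX2 and 55040086 in Connexin43-APEX2. A total RNA column of 2016, with 32640059 reads, named no line. Protein-coding genes took 23.3% to 60.1% of the reads in the bound libraries and 3.50% to 20.4% in the total RNA libraries. The footprint sheets held 185487 reads in clusters in the negative control, 575990 in APEX2-NES, 1741844 in H2B-APEX2 and 270633 in Connexin43-APEX2. The standard errors and intervals of these results cover counting error only and no variation between libraries.

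The comparison of H2B-APEX2 with APEX2-NES asks which RNAs were recovered near chromatin and which in the cytoplasm. Relative to the line's total RNA, H2B-APEX2 bound more mRNA of HNRNPA1, an RNA-binding protein that acts in splicing, with a log2 difference of 3.17 (counting SE 0.02, bound RPKM 518 against 57.5). MALAT1, a nuclear long noncoding RNA, was higher by 2.15 (SE 0.03, bound RPKM 170 against 34.0). Transcripts of genes with detained introns, which are held in the nucleus until spliced, rose as a group, with a median of 0.98 over 17 genes. Lower in H2B-APEX2 were LGALS1, which encodes galectin-1, at -4.03 (SE 0.13), and the replication-dependent histone mRNAs, with a median of -1.49 over 72 genes. The bound RPKM of LGALS1 was 57.9 in APEX2-NES and 80.2 in the negative control of 2017. Its APEX2-NES value thus did not exceed the background of the capture, and its difference cannot be read as one of place. This limit is not particular to LGALS1. The histone mRNAs of APEX2-NES also lay below the negative control relative to the median gene, as given below. Across protein-coding genes, bound RNA of APEX2-NES in 2017 correlated with that of the negative control at 0.886. Of 5055 genes tested in the 2017 table, 1267 were at least 2-fold higher and 1257 at least 2-fold lower in H2B-APEX2. Among protein-coding genes, 747 of 2859 were higher and 625 lower, and among processed pseudogenes 405 of 1166 were higher and 260 lower.

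Among protein-coding genes with reads in every library compared, the highest after FKBP3 (3.95), GGCT (3.77), PIN4 (3.53), UPF3B (3.49) and NACA2 (3.43) was RSPO1, a secreted Wnt pathway activator, at 3.34 (SE 0.08, bound RPKM 59.9 against 6.40). EIF3E, a translation initiation factor subunit, was at 3.23, GTF3C6 at 3.09 and HMGN3 at 3.08. The lowest was CST3, which encodes cystatin C, at -4.71. Its total RNA itself differed, with an RPKM of 32.3 in H2B-APEX2 and 2.61 in APEX2-NES. POLR2L (-3.93), THBS1 (-3.602), TMSB10 and ROMO1 (each -3.52), GREM1 (-3.37), RPS29 (-3.32) and S100A6 (-3.31) followed. THBS1, GREM1, LGALS1 and S100A6 belong to a set of fibroblast-like genes chosen after its values were seen. Its bound RNA was 2.70 higher in APEX2-NES than in H2B-APEX2 as a median of 21 genes. The second list, written before its values were looked at, was 2.22 higher over 21 measured genes. In hg19 HNRNPA1 (ENSG00000135486) lies on chromosome 12 from 54673977 to 54680872, and MALAT1 (ENSG00000251562) on chromosome 11 from 65265233 to 65271080.

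Some of the most extreme differences came from abundant genes listed at 0 in a library. The mitochondrial genes MT-RNR1, MT-RNR2, MT-CO1, MT-CO2 and MT-CO3, and RNU1-1, which encodes U1 small nuclear RNA, were listed at 0 in H2B-APEX2 bound RNA and at an RPKM of 455 to 26053 in APEX2-NES bound RNA. RPS2 and SNORD3A were listed at 0 in APEX2-NES total RNA. HIST2H3A, HIST2H4B, HIST2H2BE and SNORD3B-2 were listed at 0 in APEX2-NES bound RNA. SNORD3D and RPL36AL, which fell short of that abundance, also had 0 reads there. HIST2H2AA4, RNVU1-19 and PPIAL4C were listed at 0 in H2B-APEX2 total RNA, and HIST2H2AA4 also in its bound RNA. The 7SL copy RN7SL3 had a bound RPKM of 1429 in H2B-APEX2 and 0.00146 in APEX2-NES. RN7SL2, a gene of 7SL RNA of the signal recognition particle, had an RPKM of 526515 in H2B-APEX2 total RNA and 1.82 in APEX2-NES total RNA. MIR663B had a total RNA RPKM of 126 against 0.00565.

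Of the 20 gene lists, 9 had a median outside the central 95% of random lists matched on expression. Detained-intron transcripts had 8 of 17 members higher and 0 lower, with HNRNPH1 at 1.86, SRSF6 at 1.74 and SRSF7 at 1.19. Histone mRNAs had 45 of 72 members lower and 12 higher, among them HIST2H2AC at -1.68 and HIST1H3B at -1.45, while HIST1H4C was at -0.51. Without members that had 0 reads in a library, the histone median was -1.68 over 47 genes. The 6 small cytoplasmic RNAs had a median of -2.36, with RNY1 at -3.24, RNY3 at -2.86 and RN7SL1 at -1.73. Of 10 cell junction mRNAs 3 were lower, with a list median of -0.89; ACTN4, an actin crosslinker, was at -1.70, CTNNB1 at -0.90 and PDZD11 at 0.77. This list stayed inside the central 95% for bound RNA alone, at -0.21. Genes of the integrated stress, oxidative and heat shock responses had a median of -0.98, with 5 of 10 lower and 2 higher; ASNS was at 1.11, ATF4 at 0.93 and HSPA1B at -0.47. The immediate early genes CYR61 (-1.89), IER3 (-2.20) and JUN (-0.20) had a median of -1.89, and markers of other cell types one of -2.08 over 4 genes, with COL1A1 at -2.37, HBA1 at -2.13 and HBA2 at -2.02. HBA1 differed mainly in total RNA, with an RPKM of 18.0 in H2B-APEX2 and 4.46 in APEX2-NES against 0.908 and 1.37 in bound RNA, and HBA2 likewise. COL1A1 is also 1 of the fibroblast-like genes. The medians of the 13 mitochondrial mRNAs (-7.90) and of the rRNA list (-13.82) were set by genes listed at 0, and RNA5S1 of the latter was at -2.80.

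Lists inside the central 95% included nuclear long noncoding RNAs (0.79 over 6 genes), small nuclear RNAs (-1.18 over 16), ribosomal proteins (-0.91 over 84), nuclear-encoded respiratory chain subunits (0.09 over 75), zinc finger genes (0.03 over 17), secretory pathway genes (-0.28), plasma membrane genes (-0.64), protrusion mRNAs (-0.37), translation factors (0.49), glycolytic enzymes (-0.93) and snoRNA host transcripts (0.29).

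**Figure D1:**
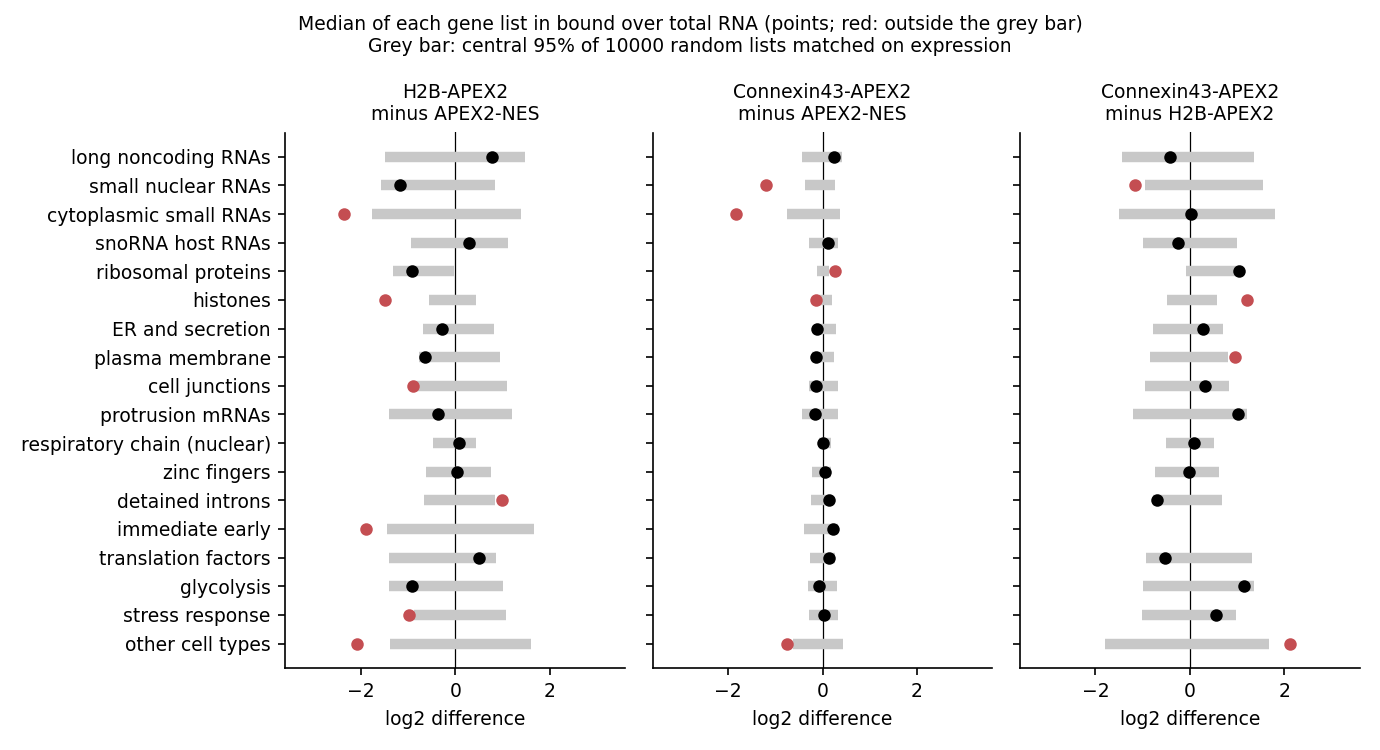
Median log2 difference of bound over total RNA for 18 gene lists (points), in H2B-APEX2 minus APEX2-NES, Connexin43-APEX2 minus APEX2-NES and Connexin43-APEX2 minus H2B-APEX2, with the central 95% of 10000 random lists of the same size and expression as grey bars. The mitochondrial and rRNA lists lie off the scale and are left out, and the immediate early list has no value in the last panel; detained-intron transcripts lie above the bar at 0.98 in the first panel.

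The GC content of transcripts moved with the difference between H2B-APEX2 and APEX2-NES. Protein-coding genes higher in H2B-APEX2 had a median GC content of 41.8%, and those lower one of 58.5%. Across 2823 genes, which are not independent replicates, the difference correlated with GC content at r = -0.66. From the lowest to the highest of 5 equal groups by GC content the median difference of bound RNA went from 1.17 to -1.08, and that of exonic footprint reads from 0.63 to -1.67. With the GC trend removed, 880 genes were at least 2-fold higher and 777 lower. The random gene lists were matched on expression and not on GC content, so a part of this trend in the list medians was not tested.

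**Figure D2:**
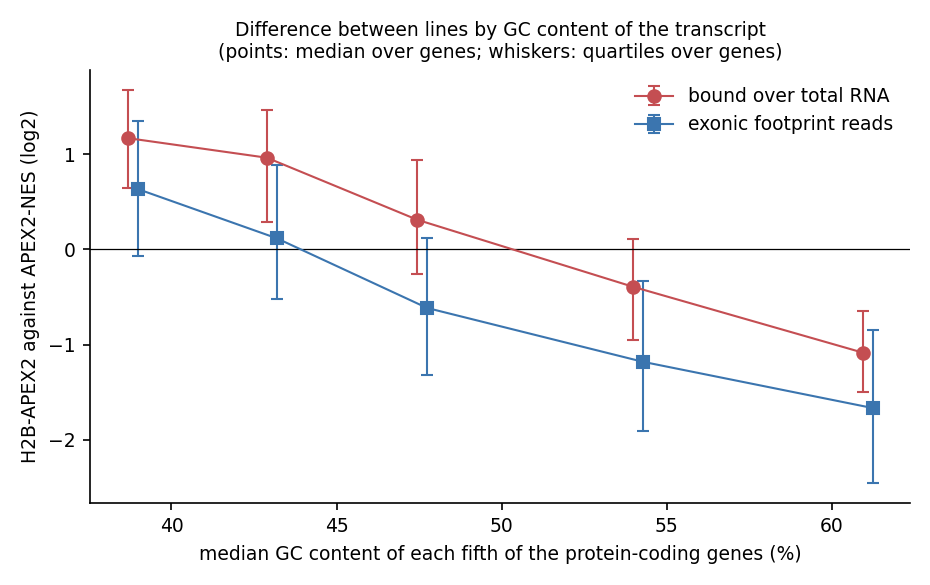
Difference between H2B-APEX2 and APEX2-NES (log2) in bound over total RNA (circles) and in exonic footprint reads (squares) for 5 equal groups of protein-coding genes ordered by the GC content of the transcript; points are medians over genes and whiskers quartiles. Both medians fall with GC content, from 1.17 to -1.08 and from 0.63 to -1.67.

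The comparison of Connexin43-APEX2 with APEX2-NES asks which cytoplasmic RNAs lay near cell contacts. Few mRNAs differed in both tables. JUND, an AP-1 transcription factor, was higher at 1.51 in 2016 and 1.23 in 2017 (SE 0.05 and 0.10). EPPK1, which encodes epiplakin, a protein that binds intermediate filaments, was at 2.01 and 1.16 (SE 0.03 and 0.05). Small noncoding RNAs were lower, such as the minor spliceosomal RNA RNU6ATAC at -2.19 and -3.61. GJA1, the gene of Connexin43 itself, was at -0.06 in each table (SE 0.07 and 0.10). Of 5594 genes tested, 11 were at least 2-fold higher in both tables and 228 lower, where chance overlap of the tables would give 8.94 and 51.0. The number higher was thus near that of chance overlap, and 45 genes differed at least 2-fold in opposite directions. The lower ones included 50 of 79 snRNA genes, 27 of 65 snoRNA genes and 72 of 3392 protein-coding genes.

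Further genes higher in both tables were NACA2 (1.34 and 1.11), PTGES3 (1.03 and 1.19) and BEX4 (1.02 and 1.36). Among the lowest were SNORA71C (-2.72 and -2.79), SNORA22 (-2.35 and -3.37), SNORA33, SNORA53 and LINC00910 (-1.99 and -2.74). TUBA1B and SNORD3A were listed at 0 in a library. The lowest protein-coding genes were MYL9, a myosin light chain (-1.997 and -2.35), DKK1 (-1.76 and -1.80), LGALS1 (-1.72 and -2.75), S100A6 (-1.71 and -2.04), THBS1 (-1.71 and -1.78), SPARC (-1.70 and -1.76), TERT (-1.69 and -1.65), PRRX2 and CLDN11. All of these belong to the first set of fibroblast-like genes, which was chosen after its values were seen. Relative to the median gene, its bound RNA was higher in APEX2-NES than in Connexin43-APEX2 by a median of 1.49 in 2016 and 0.75 in 2017. The second list, written before its values were looked at, gave 1.37 and 0.47. In 2016 the bound RPKM of LGALS1 was 36.1 in Connexin43-APEX2 and 36.2 in APEX2-NES, and that of THBS1 15.4 and 15.3. Their 2016 differences thus come from the centring, since the median gene was 1.72 higher in Connexin43-APEX2. In 2017 the bound RPKM was lower in Connexin43-APEX2, at 22.5 against 57.9 for LGALS1 and 12.1 against 24.6 for THBS1. In total RNA of 2017 the first set was 0.907 higher in Connexin43-APEX2 over 12 genes, so the 2017 differences also draw on total RNA. MALAT1 was at 0.27 and -0.38 and NEAT1 at -0.74 and -0.21.

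Small nuclear RNAs had a median of -1.20 over 17 genes, with 8 lower in both tables; among the 3 most abundant, RMRP was at -2.06 and -0.34, RPPH1 at -1.33 and -0.35, and RN7SK at -0.76 and -0.27. In total RNA the same list was 3.09 higher in Connexin43-APEX2 and 1.39 higher in APEX2-NES than in the negative control. The 6 small cytoplasmic RNAs had a median of -1.83 with 3 lower, and RNY3 was at -1.61 and -2.25 while RN7SL1 was at -1.73 and -0.73; RN7SL2 was listed at 0 in Connexin43-APEX2 bound RNA of 2017. Ribosomal protein mRNAs had a median of 0.26 and a mean of 0.01 over 85 genes, with 0 past 2-fold higher; RPS12 was at 0.77 and 0.04, RPL41 at 0.46 and 0.05, and RPS2 was listed at 0 in APEX2-NES total RNA. Histone mRNAs had a median of -0.14 with 15 of 73 lower, 17 members listed at 0, and 0.01 over the 47 members with reads in every library, with HIST1H3B at -0.19 and 0.21 and HIST1H1E at 0.14 and 0.58. Markers of other cell types were at -0.76 over 4 genes, with COL1A1 at -1.74 and -1.34, HBA1 at -1.45 and -0.09 and HBA2 at -1.46 and 0.05. Cell junction (-0.13), plasma membrane (-0.14), protrusion (-0.17) and secretory pathway (-0.12) lists lay inside the central 95%. All these values are relative to the median gene, which was itself 1.72 higher in Connexin43-APEX2 in 2016 and -0.15 in 2017; without centring, 176 genes were higher and 6 lower, the small nuclear RNA median was 0.39 in 2016 and -1.09 in 2017, the ribosomal protein median 2.08 and -0.08, and the histone median 1.49 and -0.12. In 2016 both lines share the total RNA column, so that the difference is that of bound RNA, and across 3363 protein-coding genes, which are not independent replicates, the tables correlated at r = 0.22.

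Connexin43-APEX2 was compared with H2B-APEX2 in the 2017 table to contrast cell contacts with chromatin. In Connexin43-APEX2, the ribosomal protein mRNA RPS15 was higher at 3.55 (SE 0.03, bound RPKM 123 against 14.2), as was POLR2L, a subunit shared by RNA polymerases, at 3.61 (SE 0.12). BSG, a cell surface glycoprotein, was at 2.31 and CD151, a tetraspanin named after its value was seen, at 1.89. Lower were UCHL1, a deubiquitinase, at -3.97 (SE 0.08), HNRNPA1 at -3.00, YBX1, an RNA-binding protein, at -2.83 (SE 0.02, bound RPKM 164 against 1467), and MALAT1 at -2.46. Of 4810 genes, 1210 were higher and 1154 lower, or 940 and 1468 without centring. The difference followed GC content, with r = 0.73 across 2623 protein-coding genes.

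Other high protein-coding genes were TMSB10 (3.51), TCEB2 (3.46), STRA13 (3.44), SSNA1 (3.42), COX8A (3.29), RPS19 (3.23), RPS29 (3.22) and HIST1H2AG. Other low ones were GGCT (-3.30), GTF3C6 (-3.01), MAN1A2 (-2.89), PIN4 (-2.86), SMC4 (-2.79) and HNRNPA1L2. Listed at 0 in H2B-APEX2 bound RNA were MT-RNR1, MT-RNR2, MT-CO1, MT-CO3, MT-ATP6, MT-TS1, MT-ND1 and RNU1-1, and the list medians of mitochondrial mRNAs (8.08) and of the rRNA list (13.39, RNA5S1 at 2.09) rest on that. SNORD3C, RNVU1-19, EEF1B2, PPIAL4C, RN7SL2, HIST1H4J, HIST1H2AJ and HIST2H4B were also listed at 0 in a library. Plasma membrane genes had a median of 0.96 over 14 genes, with 7 higher and 2 lower; ITGB1, an integrin, was at -1.10. Histone mRNAs were at 1.21 over 70 genes, with 41 higher and 10 lower, among them HIST1H3B at 1.74, HIST1H1E at 1.32 and HIST1H4C at 1.09. Small nuclear RNAs were at -1.17 over 17 genes, with 10 lower and 5 higher, and in bound RNA alone at 1.87; the 3 most abundant were RN7SK at 1.03, RPPH1 at 2.41 and RMRP at 3.17. Markers of other cell types were at 2.11, with HBA1 at 2.11, HBA2 at 2.14 and COL1A1 at 1.10. HBA1 again differed mainly in total RNA, with an RPKM of 5.06 in Connexin43-APEX2 and 18.0 in H2B-APEX2 against 1.24 and 0.908 in bound RNA, and HBA2 likewise.

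Bound RNA of each APEX2 line was set against that of the negative control, the background of the streptavidin capture. In H2B-APEX2, YBX1 was higher at 4.17, SRP9, a signal recognition particle protein, at 4.08, HNRNPA1 at 3.96, and NPM1, the nucleolar protein nucleophosmin, at 3.71. LGALS1 was lower at -4.70. For Connexin43-APEX2, EEF2, a translation elongation factor, was at 1.63 in 2016 and 1.99 in 2017, and PABPC1, a poly(A)-binding protein, at 1.58 and 1.93. For APEX2-NES, VAMP8 was at 1.76 and 1.65 and RPS16 at 1.88 and 1.09, though at 0.13 and 1.49 and at 0.25 and 0.93 without centring. The genes past 2-fold numbered 1901 higher and 1298 lower of 7543 for H2B-APEX2, 282 higher and 229 lower of 11289 for Connexin43-APEX2 (chance overlap 104 and 94.6), and 153 higher and 95 lower of 9266 for APEX2-NES (chance overlap 40.9 and 45.9). Of 1258 processed pseudogenes 605 were higher and 144 lower for H2B-APEX2. Connexin43-APEX2 and APEX2-NES had to pass in both tables. By the 2017 values alone, over the same genes, Connexin43-APEX2 had 739 higher and 701 lower and APEX2-NES 549 and 707. At least 2-fold in opposite directions in the tables were 130 and 162 genes. Across protein-coding genes the tables correlated at r = 0.35 and 0.12. Bound RNA of 2017 correlated with that of the negative control at 0.886 in APEX2-NES, 0.874 in Connexin43-APEX2 and 0.593 in H2B-APEX2.

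Ribosomal protein mRNAs were above random lists in Connexin43-APEX2 (median 0.96 over 86 genes, 28 past 2-fold higher and 0 lower) and in APEX2-NES (0.62, 5 higher and 0 lower). Nuclear-encoded respiratory chain mRNAs were at 0.32, 0.26 and, in H2B-APEX2, 0.75, with 36 of 77 higher there. Histone mRNAs were at -0.40 in Connexin43-APEX2, -0.43 in APEX2-NES and -1.52 in H2B-APEX2, where 54 of 71 were lower. Detained-intron transcripts were at 0.99 in H2B-APEX2, with 10 of 20 higher and 0 lower. Mitochondrial mRNAs went from 0.86 in 2016 to -2.08 in 2017 in APEX2-NES and from 0.83 to -2.17 in Connexin43-APEX2. Small nuclear RNAs were at -0.65 in Connexin43-APEX2 and -1.55 in H2B-APEX2, and small cytoplasmic RNAs at -1.28 and -2.88. Connexin43-APEX2 also had snoRNA host transcripts at 0.57, secretory pathway genes at -0.40 and zinc finger genes at 0.15 (-0.11 without centring). H2B-APEX2 also had plasma membrane genes at -0.83, immediate early genes at -0.99 and integrated stress, oxidative and heat shock genes at -0.85, and APEX2-NES translation factors at 0.35 (-0.55 without centring). These values are relative to the median gene; without centring, the split was 11 higher and 724 lower in APEX2-NES, 117 and 496 in Connexin43-APEX2 and 1526 and 1891 in H2B-APEX2. In APEX2-NES the ribosomal protein median was then -0.28 and the respiratory chain median -0.64, while in Connexin43-APEX2 they were 0.70 and 0.06.

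Bound was compared with total RNA within each line, where the labels give depletion of rRNA for total RNA and none for bound RNA. The 2016 total RNA column had 23.8% of its reads in genes of rRNA type, the other libraries 0.00120% to 4.85%. MALAT1 was higher in bound RNA in every line, at 3.78 in H2B-APEX2, 2.85 and 2.20 in APEX2-NES, 3.44 and 1.39 in Connexin43-APEX2, and 4.23 and 1.95 in the negative control. Mitochondrial mRNAs had a median of 5.41 in the negative control, 2.66 in APEX2-NES and 2.41 in Connexin43-APEX2, and were listed at 0 in H2B-APEX2 bound RNA. In the negative control 11 of the 13 were listed at 0 in a library, and the median was 1.06 in 2016 and 10.39 in 2017, where 4 of 37 mitochondrial genes had reads in its total RNA. Histone mRNAs were at 1.36, 1.03 and 0.52 in the first 3 of these lines. Respiratory chain mRNAs were at -1.25 in the negative control, -0.70 in APEX2-NES, -0.74 in Connexin43-APEX2 and -1.32 in H2B-APEX2, though at 0.30, -0.07, 0.74 and -0.61 without centring. In H2B-APEX2, RSPO1 (4.81) was high, RPS29 (-6.69) and RPS19 (-5.61) low, detained-intron transcripts at 1.02 (9 of 17 higher) and ribosomal protein mRNAs at -3.19 (66 of 83 lower). Higher and lower genes numbered 964 and 1707 in H2B-APEX2, 216 and 402 in Connexin43-APEX2, 214 and 211 in APEX2-NES, and 456 and 526 in the negative control. Without centring the same splits were 2194 and 1222, 1165 and 66, 937 and 38, and 2786 and 33. H2B-APEX2 stands in the 2017 table only, while the other lines had to pass in both tables. By the 2017 values alone, centred, Connexin43-APEX2 had 579 higher and 1398 lower, APEX2-NES 1078 and 1103, and the negative control 1110 and 2088. Chance overlap of the tables would give 87.3 and 128, 106 and 113, and 177 and 213 in these 3 lines.

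Total RNA of the APEX2 lines was compared with that of the negative control in 2017. GJA1 had 57 reads in Connexin43-APEX2, 46 in the negative control, 44 in APEX2-NES and 11 in H2B-APEX2. Its RPKM was 0.243 in Connexin43-APEX2 and 0.194 in the negative control, so that GJA1 did not set apart the line named for Connexin43 in these tables. Small nuclear RNAs were higher in all 3 lines, with medians of 3.09 in Connexin43-APEX2 (15 of 17 past 2-fold), 1.39 in APEX2-NES (14 of 16) and 0.59 in H2B-APEX2 (2 of 16). Small cytoplasmic RNAs were at 3.59, 1.16 and 0.83. Among protein-coding genes, DNPH1 was at 1.92 and GADD45GIP1 at -2.48 in H2B-APEX2. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 were listed at 0 in total RNA of the negative control. Genes past 2-fold were 437 higher and 224 lower in Connexin43-APEX2, 241 and 154 in APEX2-NES, and 82 and 80 in H2B-APEX2. Without centring these splits were 314 and 659, 151 and 416, and 63 and 164.

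Footprints of RNA-binding proteins were compared by the part of the transcript they covered. In H2B-APEX2, 39.6% (95% interval 39.3 to 39.8, exact Clopper-Pearson) of 133881 clusters lay in introns. The share was 5.58% (5.37 to 5.79) of 45015 clusters in APEX2-NES, 9.47% (9.09 to 9.85) of 23104 in Connexin43-APEX2 and 14.1% (13.6 to 14.6) of 20850 in the negative control. Coding sequence held 23.2% in H2B-APEX2, 42.7% in APEX2-NES, 41.0% in Connexin43-APEX2 and 37.7% in the negative control, and 3' UTRs held 27.4%, 38.3%, 36.3% and 37.8%. In reads rather than clusters, the intron share was 19.9%, 3.94%, 9.80% and 10.4%. MALAT1 held 0.993% of the footprint reads in H2B-APEX2, 0.0698% in APEX2-NES, 0.205% in Connexin43-APEX2 and 0.60004% in the negative control. Mitochondrial genes held 17.9%, 5.17%, 5.67% and 11.5%.

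**Figure D3:**
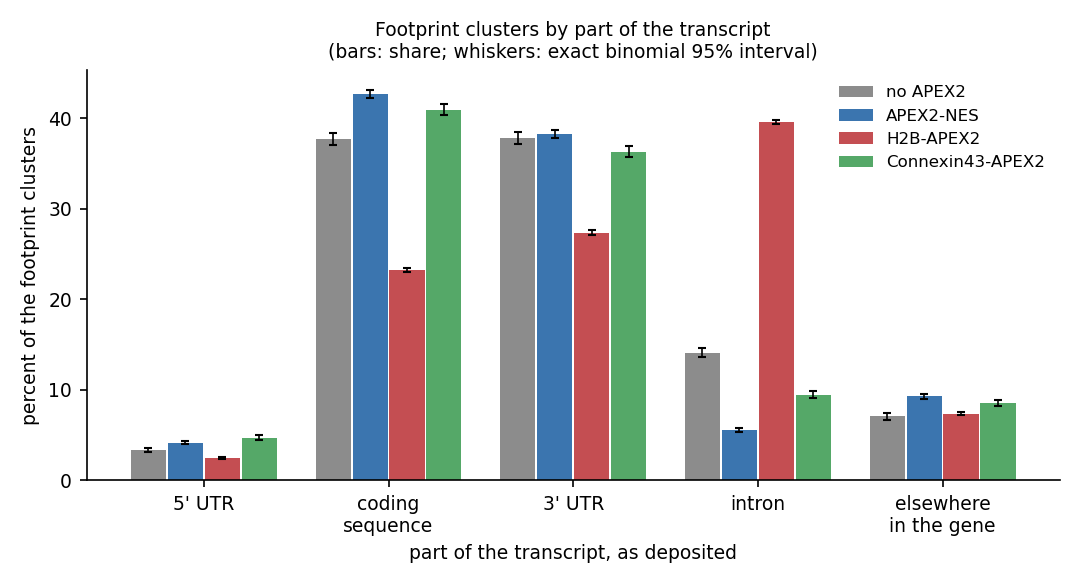
Percent of footprint clusters in each part of the transcript, as deposited, for the 4 lines (bars, 1 library each), with exact binomial 95% intervals. Introns hold 39.6% of the clusters in H2B-APEX2 and 5.58% to 14.1% in the other 3 lines.

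Per gene, footprint reads of H2B-APEX2 and APEX2-NES were compared as shares of their totals. ERI3, an exoribonuclease gene, was higher in H2B-APEX2 at a log2 ratio of 5.04 (95% interval 3.68 to 6.93), with 66 of its 71 clusters in introns. MALAT1 was at 3.83 (3.69 to 3.98), with 17290 reads in 10 clusters against 402 in 25. Against the negative control it was at 0.726 in H2B-APEX2, short of the 4-fold rule, and at -3.10 in APEX2-NES. MALAT1 thus differed mostly by its low share in APEX2-NES. For footprints it was listed without coordinates and under an Ensembl identifier other than that given for its RNA. ZNF383 (5.22) and EIF3F (5.01) were also high. The highest ratio was that of WDR74 on chromosome 11 from 62599814 to 62609281, at 7.81 (7.23 to 8.45). Of its 16267 reads in H2B-APEX2, 16202 lay outside its annotated UTRs, coding sequence and introns, and RNU2-2P, a U2 snRNA gene, overlaps it from 62609091 to 62609281. Lowest were MRPL34 (-6.50), CEBPB (-6.31), COX8A (-6.23), GPX4 (-5.97) and PPP1CA (-5.93). Of 7478 genes compared, 617 were higher and 871 lower by the 4-fold rule, and 1634 had reads in H2B-APEX2 only against 110 in APEX2-NES only.

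In footprint reads, those in introns included, detained-intron transcripts were above random lists, with a median of 0.98 over 27 genes, 7 higher and 0 lower. These random lists were matched on read numbers and not on GC content. In H2B-APEX2 54.3% of their clusters were intronic, against 12.4% in APEX2-NES, where the shares over all genes were 39.6% and 5.58%. Mitochondrial mRNAs, listed at 0 in H2B-APEX2 bound RNA, were at 1.55 over 10 genes in footprints. Glycolytic enzymes (-1.66), immediate early genes (-1.43), histones (-1.23) and integrated stress, oxidative and heat shock genes (-1.13) were below random lists. Across 2168 genes, which are not independent replicates, footprint and bound RNA differences correlated at r = 0.48, with exonic footprint reads at 0.44 across 1979. With the trend with GC content removed from both, this r was 0.12 across 1978 genes, and within 5 equal groups by GC content it ran from -0.02 to 0.22.

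For Connexin43-APEX2 against APEX2-NES, 238 of 5541 genes were higher and 154 lower, while 194 had reads in the former only and 1158 in the latter only. Respiratory chain mRNAs were at 0.54 over 49 genes, with 3 higher and 1 lower. CENPP, a kinetochore protein gene on chromosome 9 from 95087766 to 95382815, was highest at 7.35 (6.99 to 7.72), and its 4891 reads formed 1 intronic cluster. PCCA (5.91), ARHGAP21 (5.04), NR3C2 (5.00) and RPS6 (4.58) followed, and UBAP1 (-4.31), KXD1 (-4.27), HIST1H2AI (-3.82), MOB1A (-3.81) and ZNF614 (-3.72) were lowest. Footprint and bound RNA differences were unrelated across 2371 genes (r = 0.01). Against H2B-APEX2, Connexin43-APEX2 had 885 genes higher and 328 lower of 6002; STK32C (7.14), RYR2 (7.04), SNRPD2 and SLC25A5 (each 6.88) and CENPP (6.59) were highest and TNPO1 (-4.74), RABEP1 (-4.56), LARP4 (-4.44), PSMD12 (-4.41) and ACBD3 (-4.28) lowest. With ratios centred on their median, that split was 594 and 536. Left out of it were 58 genes with reads in Connexin43-APEX2 only and 2984 with reads in H2B-APEX2 only. Glycolytic enzymes were at 1.72, integrated stress, oxidative and heat shock genes at 1.36, detained-intron transcripts at -0.996 and mitochondrial mRNAs at -1.80.

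Against the negative control's footprints, 117 genes were higher and 521 lower of 5865 in H2B-APEX2, 186 and 339 of 5313 in APEX2-NES, and 186 and 262 of 4580 in Connexin43-APEX2; centred on the median, the first 2 splits were 253 and 349, and 239 and 281. These splits leave out genes with reads in only 1 line of the pair, and the control had the fewest footprint reads (185487). Such genes numbered 3041 in H2B-APEX2 only against 24 in the control only. They numbered 1366 against 141 for APEX2-NES, and 673 against 455 for Connexin43-APEX2. HIST1H1E, a linker histone gene, was higher in APEX2-NES (5.43) and H2B-APEX2 (4.79). CKS2, a cyclin-dependent kinase subunit, was higher in APEX2-NES (4.21) and Connexin43-APEX2 (4.80). FAR1 was highest in H2B-APEX2 at 4.82, with 70 of 108 clusters intronic. COX8A was at -7.44 in H2B-APEX2, KIAA0430 at -5.59 in APEX2-NES and TNPO1 at -4.87 in Connexin43-APEX2.

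Fibroblast-like genes were compared between bound libraries, since they filled the lowest places in Connexin43-APEX2 against APEX2-NES. THBS1, which encodes thrombospondin-1, had a bound RPKM of 171 in the negative control of 2016 and 34.5 in that of 2017, 15.3 and 24.6 in APEX2-NES, 15.4 and 12.1 in Connexin43-APEX2, and 0.632 in H2B-APEX2. A second list of 39 such genes, 34 of them measured, was, relative to the median gene, 1.14 higher in the negative control than in APEX2-NES in 2016, with 20 past 2-fold higher and 0 lower.

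**Figure D4:**
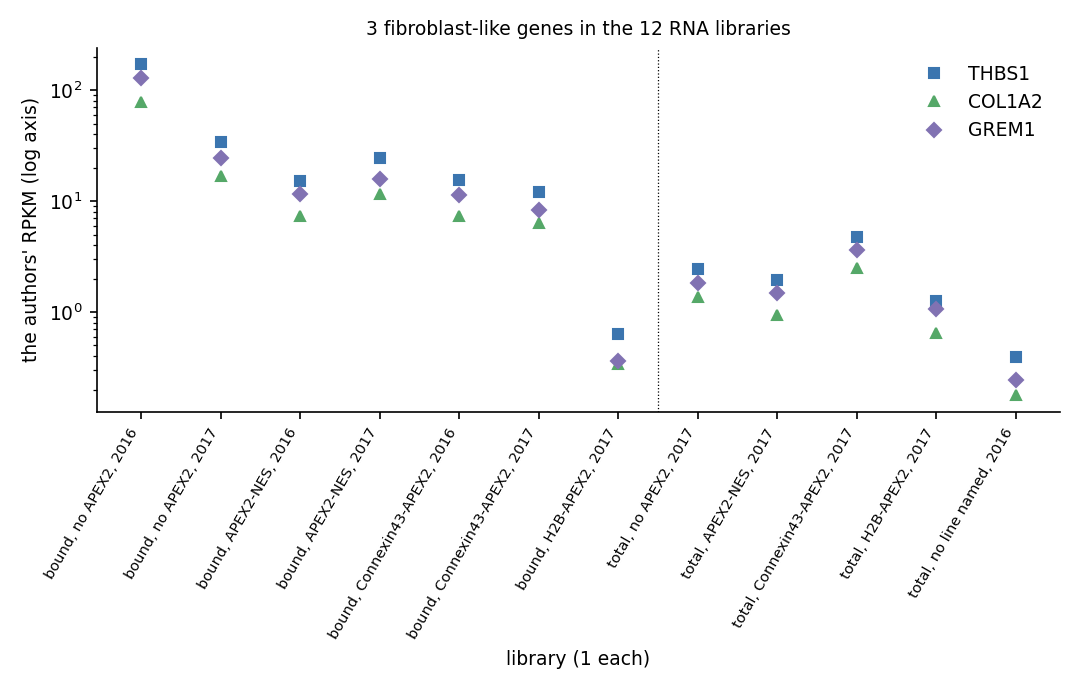
RPKM (log axis) of THBS1, COL1A2 and GREM1 (3 symbols) in the 7 bound and 5 total RNA libraries, 1 point per library and gene. The 3 genes move together, highest in bound RNA of the negative control in 2016, where THBS1 is at 171, and in bound RNA lowest in H2B-APEX2.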

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

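Of the tests below, those of mitochondrial copies, other pseudogenes and missing mitochondrial RNA, of total RNA against GC content, of a lasting line difference and of matrix binding were chosen only after the result was seen. The thresholds for total RNA against GC content and for a lasting line difference were also rewritten after their values were seen. A difference between lines called attention to mitochondrial mRNAs. Their median bound minus total RNA was 2.41 in Connexin43-APEX2, 2.66 in APEX2-NES and 5.41 in the negative control, and -5.29 in H2B-APEX2, so that the lines differed from H2B-APEX2 by 7.70, 7.95 and 10.7. Each difference was not tested, since each line had 1 library per table. Its size depends on the pseudocount, because the genes were listed at 0 in H2B-APEX2 bound RNA. The control's 5.41, and so the 10.7, rests on 0 values as well, since 22 mitochondrial genes were listed at 0 in its total RNA of 2017.

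Absence of mitochondrial RNA near chromatin was weighed for these 0 values. Mitochondrial genes and their nuclear copies together took 16.5% of the reads of that library. This was 1.87 times the lowest share in another bound library, 8.79% in the negative control of 2016. The other bound libraries of 2017 held more, at 21.6% in APEX2-NES, 25.2% in Connexin43-APEX2 and 50.7% in the negative control. Whether reads listed under nuclear copies are mitochondrial RNA is itself the question, so this share cannot decide whether mitochondrial RNA was missing. The nuclear copies alone took 16.5% of the bound RNA reads of H2B-APEX2, 2.41 times the highest other share (6.83%). Reads of mitochondrial origin may thus have been assigned to the copies. Other processed pseudogenes took 15.4%, 1.57 times the highest other share (9.80%), so that a different alignment or annotation of that library, which would bear on every H2B-APEX2 difference in RNA, cannot be told apart from it. Assignment to the copies and a different alignment or annotation stay open. The reads were not analysed here, and true transcription of these genes was not measured.

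AT-rich mRNAs were high and GC-rich ones low in H2B-APEX2 bound RNA. Recovery by GC content in that bound library alone would leave the footprints unaffected, yet exonic footprint reads of H2B-APEX2 against APEX2-NES correlated with GC content at -0.511 across 6788 genes, which are not independent replicates. Total RNA argues against a difference of the cells or lysate as a whole, for the 1787 genes compared there. Its correlation with GC content was 0.259 for H2B-APEX2 minus APEX2-NES, while bound RNA alone had -0.588 across 3933 genes. Total RNA of H2B-APEX2 minus the negative control had -0.305, between those of APEX2-NES (-0.382) and Connexin43-APEX2 (-0.256). AT-rich mRNAs may lie nearer to the nuclear bait, a hypothesis that needs the footprint correlation of -0.511. GC-dependent recovery common to the streptavidin preparations of that line was not tested and stays open.

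Fibroblast-like genes were high in the negative control's bound RNA of 2016. RNA of another, fibroblast-like cell type could account for the excess, as a second marker list was higher by 1.14 than in APEX2-NES, at percentile 100 of random lists. A lasting difference between the lines cannot be told apart from it, since the excess fell by 1.07 from 2016 to 2017 (paired over 30 genes 1.14, bootstrap 95% interval over genes 0.950002 to 1.43) but the variation between libraries was not measured. HEK293 mRNAs that bind the streptavidin matrix without biotin cannot be told apart from it either, since that list differed by up to 0.777 (percentile 99.3, 8 genes) between total RNA libraries of 2017 and the 2016 table has no total RNA per line.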

How the results depend on the processing

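The GC trend removal, TMM or size factors together with centring, leaving out fibroblast-like genes and leaving out genes listed at 0 were chosen only after the results were seen, and the other alternatives were planned. Of 377 alternative values of 59 list medians in the 3 comparisons between APEX2 lines, none of them without centring, 325 kept their direction and their side of the central 95%, 17 moved inside it, 33 moved outside it and 2 reversed. Of 181 alternative counts and shares, 113 stayed within 1.5 times the reported value (shares: within their interval) and 68 moved; the cause was not tested unless a smaller number of tested genes shows it. The labels pair no samples. Lines were compared within each table, and the limma fit had a term for the table. List medians without centring, several of which change sign, stand with the results and are not counted here.

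With a pseudocount of 5, genes past 2-fold numbered 1222 in H2B-APEX2 minus APEX2-NES, 23 in Connexin43-APEX2 minus APEX2-NES, 1116 in Connexin43-APEX2 minus H2B-APEX2, 70, 120 and 1298 in bound RNA of APEX2-NES, Connexin43-APEX2 and H2B-APEX2 against the control, 328, 119, 237 and 1503 in bound minus total RNA of the control, APEX2-NES, Connexin43-APEX2 and H2B-APEX2, and 234, 394 and 83 in total RNA of APEX2-NES, Connexin43-APEX2 and H2B-APEX2. With 0.1, Connexin43-APEX2 minus APEX2-NES gave 434, bound RNA of APEX2-NES and Connexin43-APEX2 against the control 541 and 1245, bound minus total RNA of the control, APEX2-NES and Connexin43-APEX2 2139, 1420 and 1532, and H2B-APEX2 total RNA 285.

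At a mean RPKM of at least 5, which tests fewer genes, the first 3 comparisons gave 1248, 122 and 1214, bound RNA against the control 121, 302 and 1389, and bound minus total RNA 283 in APEX2-NES and 1461 in H2B-APEX2. The lists outside the central 95% fell to 5, 3 and 3. Without a filter, APEX2-NES against the control gave 625, bound minus total RNA of the control, APEX2-NES and Connexin43-APEX2 2774, 949 and 1171, and total RNA 1033 in Connexin43-APEX2 and 259 in H2B-APEX2. Without centring, the same bound minus total comparisons gave 2819, 975 and 1231, and APEX2-NES against the control 735. With TMM factors and centring, Connexin43-APEX2 minus APEX2-NES gave 159 of 3679 genes, and with size factors and centring 158 of 3686; without centring these were 176 and 166.

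Connexin43-APEX2 minus APEX2-NES had 623 genes and 9 lists in the 2016 table alone, 735 genes and 3 lists in 2017 alone, where histone mRNAs reversed to 0.0416, and 99 genes (16 higher and 83 lower) and 10 lists for bound RNA alone. Division by the control's bound RNA cancels within each gene and changes only the genes tested and the median, with 99 genes (32 higher and 67 lower). Bound RNA alone also reversed small nuclear RNAs in Connexin43-APEX2 minus H2B-APEX2, to 1.87. With the GC trend removed, H2B-APEX2 minus APEX2-NES gave 1657 genes and Connexin43-APEX2 minus H2B-APEX2 1349. limma over both tables called 0, 0 and 0 genes at an adjusted p under 0.05 in the first 3 comparisons, and 1721, 430 and 1444 of 6800 had an unadjusted p under 0.05 with 2 residual degrees of freedom.

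For genes with at least 10 footprint reads, the 3' UTR share of clusters was 39.0% in the control, 38.8% in APEX2-NES and 37.2% in Connexin43-APEX2, and the intron share in Connexin43-APEX2 9.04%. Relative to bound RNA, which fewer genes have, footprints past 4-fold numbered 550, 159 and 414 in the first 3 comparisons and 273 and 253 in APEX2-NES and Connexin43-APEX2 against the control. With a minimum of 50 reads they numbered 238 in Connexin43-APEX2 against APEX2-NES, and 272, 364 and 247 in APEX2-NES, H2B-APEX2 and Connexin43-APEX2 against the control. Leaving out runs, and long and short footprints apart were not run.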

Other observations

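No test in this part was chosen to explain a value. The total RNA column of 2016 that named no line stood apart from the total RNA of 2017. Protein-coding genes took 3.50% of its reads against 11.9% to 20.4% in the others, and mitochondrial genes 21.0003% against 0.00691% to 0.686%.

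In total RNA of the negative control 4 of 37 mitochondrial genes had reads, against 23 in H2B-APEX2, 26 in Connexin43-APEX2 and 27 in APEX2-NES. Bound RNA of the negative control had mitochondrial genes at 7.34% of reads in 2016 and 43.8% in 2017.

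Glycolytic enzyme mRNAs were low in Connexin43-APEX2 total RNA against the control, with a median of -0.61 over 11 genes, and nuclear-encoded respiratory chain mRNAs were at -0.37 over 71. Secretory pathway mRNAs were at 0.26 over 28 genes in H2B-APEX2 total RNA. Ribosomal protein genes had 65.6% of their footprint clusters in introns in H2B-APEX2, 23.3% in APEX2-NES and 25% in the negative control, and glycolytic enzymes 78.3%, 19.4% and 44.6%. Over all genes these shares were 39.6%, 5.58% and 14.1%.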
